A study of Helianthus annuus with 15 samples.

How the data were processed

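RNA from root, stem, leaf, flower and axil of sunflower was sequenced in 15 libraries, 3 per tissue, and samples were grouped by the tissue in their labels. Per the labels' protocols, mRNA was captured on oligo(dT) beads, fragmented, reverse transcribed, ligated to adaptors with molecular identifiers and amplified by PCR. Selection by oligo(dT) lowers the share of RNA without a poly(A) tail, so organelle and noncoding RNA are measured only as far as they passed it. Whether molecular identifiers were used in counting is not given in the sources used here, so counting limits cover counting error only.

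The deposited values are FPKM, computed by the authors for each library, with further columns holding the authors' mean FPKM per tissue. HTSeq 0.6.1 is named in the submitters' processing notes. The aligner, genome build and annotation are not given in the sources used here. Beside the deposited FPKM table stand other cells, in which 1 identifier is paired with the name NAC83 and its 15 values are repeated. A further 18 unnamed columns were not used. None of the identifiers (0) matched the reference gene table of assembly HanXRQr2.0-SUNRISE, so no names or coordinates were taken from it. Chromosome numbers are those written in the identifiers.

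Depth was recovered from the FPKM values. Within a gene, values are whole multiples of what 1 read is worth in a library. The whole reads behind them, and so the library totals, were solved for all 63411 rows. Gene lengths followed for rows with reads, and the 12844 rows at 0 in all libraries imply none. A value counted as whole within 1e-06 plus 5e-07 of the number of reads, or within 0.001 in a wider search used for 90 rows. The implied gene lengths were whole numbers within 0.05 nt for 100% of the 17278 tested, where chance gives 10%. On simulated reads the procedure returned the exact reads for 96.2% of 49361 genes and for 99.4% of the 44776 genes with reads in at least 3 libraries. Of the genes tested, 114 had an implied length below 100 nt, where FPKM magnifies small numbers of reads. Pairs of replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 9.58 to 66.1, so no library was counted as a repeat of another.

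Genes with at least 1 FPKM in at least 3 libraries were tested, 34586 in all. Values were transformed to log2(FPKM + 1) from the deposited FPKM and fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend) on all 15 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Genes higher in a tissue than in each other one passed in all 4 pairwise comparisons. On simulated data with 3 libraries per tissue, the axil to stem comparison recovered 7% of 100 genes changed 2-fold and 68% of 100 changed 4-fold, with 4 unchanged genes called among 32667. The test for genes higher in axil than in each other tissue recovered 2% and 73%, with 0 unchanged genes called among 32616. A 2-fold change lies at the log2 difference of 1 that a call requires, and the pseudocount shrinks it further, which lowers its recovery. With limma's voom on the simulated reads, which does not use that pseudocount, 2-fold changes were recovered at 18% and 8% in these 2 tests. The simulation does not separate the effect of the threshold from that of the spread between libraries. It changed only 100 genes at each fold, in axil alone, whereas 82.9% of the genes tested differed among tissues in the data. The Benjamini-Hochberg adjustment is stricter when few genes change, so these recovery rates do not carry over to the real comparisons. Classes of identifiers were tested with camera at a preset correlation of 0.01 and with an estimated one. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

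The design, the rule for named genes and the processing settings to be varied were fixed before the data were examined. That rule took the genes with the largest margin per tissue and the largest differences per axil comparison, among those with at least 5 FPKM, no overlap between the groups and an informative product name. Because the table gives no product names, the last condition was dropped, and at most 2 identifiers in each direction were taken per comparison. The gene lists fixed beforehand, and the TCP transcription factor genes in the study's title, matched 0 identifiers and were not analysed here. Alternatives covered the pseudocount, the filter, scaling, the variance model, a replicate block, the fold threshold, the libraries in the fit and leaving out each library. Leaving out a library was run first with the filter recomputed on the remaining 14. After the root count was seen to fall, it was run again with the filter kept from all 15, and both are given.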

Results

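Gene expression was profiled by mRNA sequencing in 5 tissues of sunflower (Helianthus annuus), namely root, stem, leaf, flower and axil, with 3 libraries per tissue and 15 in all. The axil is the angle between a leaf and the stem, where side shoots start. The deposited FPKM table listed 63411 gene identifiers, of which 12844 were at 0 in all libraries. Between 12084975 and 14727843 reads per library were recovered from the steps between FPKM values. At that depth, 3 reads on a gene of 1000 nt correspond to 0.204 to 0.248 FPKM, depending on the library. The labels do not say whether the 3 libraries of a tissue came from separate plants, so p-values measure the spread between these libraries, which may be technical. Genes are given by the identifiers of the table, which pairs only 1 of them with a name.

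The first question was how far the tissues differ from one another. By median correlation, root stood apart from the 4 shoot tissues, least clearly from the axil, and the axil lay closest to leaf and stem. Across the genes tested, the median Pearson correlation of log2(FPKM + 1) was 0.819 between axil and leaf libraries and 0.814 between axil and stem libraries. It was 0.738 between axil and flower and 0.706 between axil and root. The ranges over pairs of libraries overlapped, from 0.685 to 0.763 with flower and from 0.690 to 0.737 with root. Axil 3 alone had a higher mean correlation with root (0.724) than with flower (0.697). Stem and flower libraries correlated at 0.818, whereas root and flower, the least similar pair, correlated at 0.517. Libraries of the same tissue correlated at a median of 0.916 in leaf and up to 0.977 in flower. These correlations are across genes, which are not independent replicates. In a principal component analysis the first component held 42.8% of the variance and separated root from the shoot, and the second held 21.3% and separated leaf and axil from flower, stem and root.

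**Figure D1:**
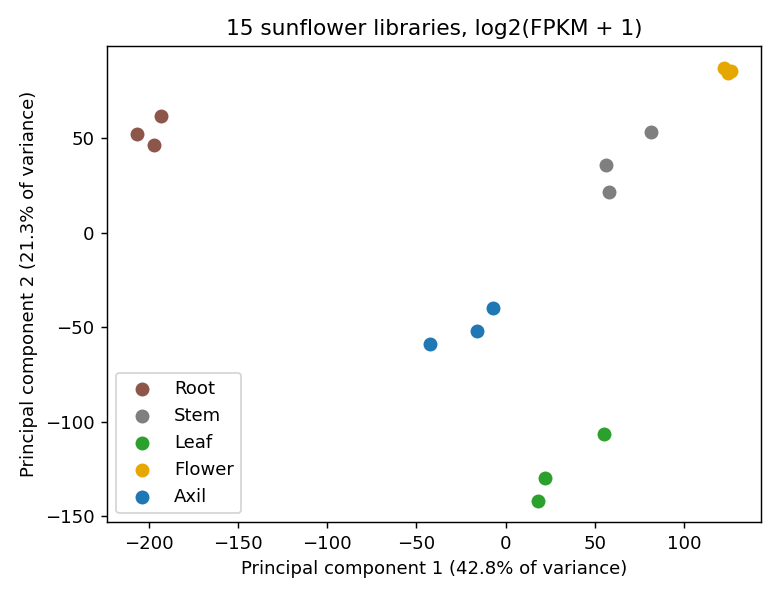
Principal component 1 (horizontal axis, 42.8% of the variance) against component 2 (vertical axis, 21.3%) of log2(FPKM + 1), with 1 point per library and 3 libraries per tissue. The root libraries lie between -206 and -193 on component 1, and the axil libraries lie between root and the other shoot tissues, from -42.5 to -7.28.

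Most genes varied between tissues. Of 34586 genes tested, 28667 (82.9%) differed among the 5 tissues in limma's moderated F test after Benjamini-Hochberg adjustment. This F test used no fold threshold, whereas the counts between pairs of tissues also required an absolute log2 difference of at least 1. Between pairs of tissues, stem and flower differed in the fewest genes, 6080 (17.6% of those tested). Root and flower differed in the most, 13221 (38.2%). Leaf and axil differed in 6325 genes, stem and axil in 6988, root and axil in 8616 and flower and axil in 9305. Expression in all tissues was common: 21349 genes had a mean of at least 1 FPKM in all 5, and 5323 reached that level in exactly 1. The number of genes with a mean of at least 1 FPKM was similar across tissues, from 27771 in leaf to 28524 in axil.

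The next comparison set each tissue against all others. Root had the most genes higher than in each other tissue, 2509, followed by flower with 1565, leaf with 1155, stem with 903 and axil with 589. Strong restriction to a single tissue was rarer. A mean of at least 10 FPKM in 1 tissue, with under 1 FPKM in each library of the others, was found for 236 genes in root, 109 in flower, 49 in leaf, 11 in stem and 11 in axil. When 1 root library was left out and the filter on low values was recomputed on the remaining 14, the root count was 1596 without Root 1, 1585 without Root 2 and 1639 without Root 3. The filter kept from all 15 libraries was an alternative chosen after those values were seen. With it, the root count lay between 2445 and 2567 when each of the 15 libraries was left out in turn.

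In root, HannXRQ_Chr16g0505511 on chromosome 16 reached 1404 ± 304 FPKM (SD, n = 3), and its highest value in the other 12 libraries was 2.56. HannXRQ_Chr10g0314091 on chromosome 10 reached 985 ± 499 FPKM (SD, n = 3) in root and at most 0.340 elsewhere. In flower, HannXRQ_Chr17g0559971 on chromosome 17 stood at 7578 ± 336 FPKM (SD, n = 3) and at 0.433 ± 0.215 (SD, n = 3) in leaf, the tissue closest to it. HannXRQ_Chr07g0191671 on chromosome 7 stood at 3062 ± 788 FPKM (SD, n = 3) in flower and at most 1.64 elsewhere. In leaf, HannXRQ_Chr17g0567431 was measured at 107 ± 8.04 FPKM (SD, n = 3), with a highest value of 0.856 in the other tissues. HannXRQ_Chr12g0356131 was at 316 ± 116 FPKM (SD, n = 3) in leaf and at 2.88 ± 1.85 (SD, n = 3) in root, the tissue closest to it (1.82 without Root 2). In stem, HannXRQ_Chr17g0550041 was at 175 ± 47.7 FPKM (SD, n = 3) and HannXRQ_Chr16g0498381 at 94.6 ± 17 (SD, n = 3), against highest values of 8.22 and 5.12 in other tissues. In axil, HannXRQ_Chr12g0377421 on chromosome 12 reached 664 ± 101 FPKM (SD, n = 3), with at most 22.0 elsewhere. HannXRQ_Chr15g0489891 on chromosome 15 reached 303 ± 97.4 FPKM (SD, n = 3), with at most 12.6 elsewhere. HannXRQ_Chr10g0314091, HannXRQ_Chr17g0567431 and HannXRQ_Chr17g0559971 stayed under 1 FPKM outside their tissue. Each therefore failed the recomputed filter when a library of that tissue was left out.

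**Figure D2:**
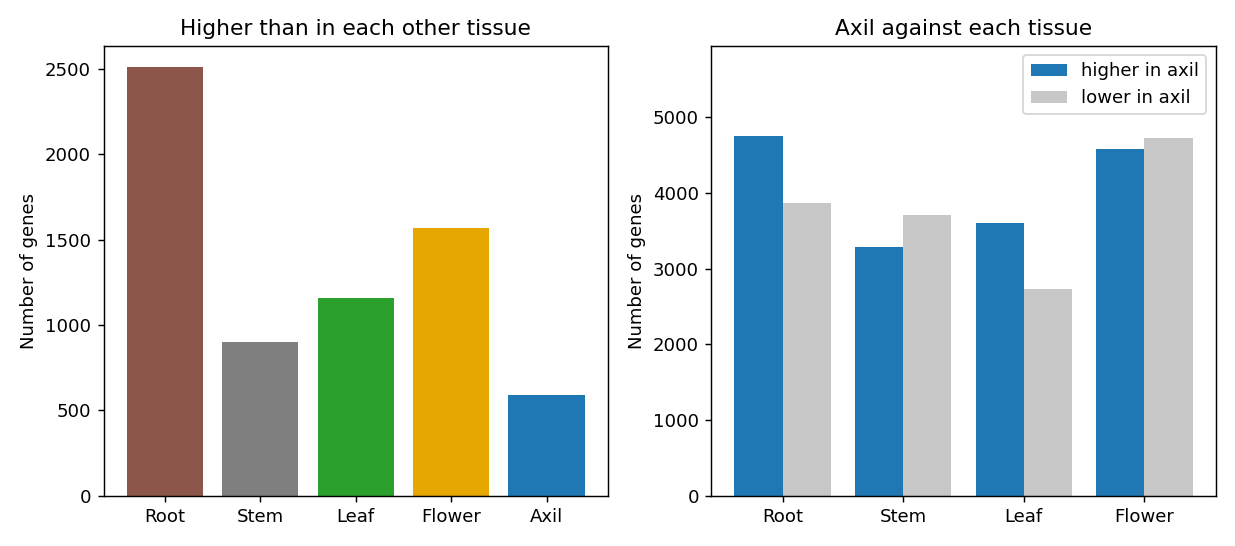
Left, the number of genes (vertical axis) higher in each tissue than in each of the other 4, which is 2509 in root and 589 in axil. Right, the number of genes higher (blue) or lower (grey) in axil than in root, stem, leaf or flower, from limma with 3 libraries per tissue, with 4753 higher and 3863 lower against root as deposited and 4195 and 4176 after median-of-ratios scaling.

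The title of the study concerns shoot branching, so the axil was then set against each other tissue. A gene named for 1 of these comparisons need not be particular to the axil. Against root, 4753 genes were higher in axil and 3863 lower, an excess that nearly vanished after quantile normalization (4279 and 4251) and median-of-ratios scaling (4195 and 4176). HannXRQ_Chr16g0506961 was at 1751 ± 1040 FPKM (SD, n = 3) in axil and 0.0341 ± 0.0591 (SD, n = 3) in root, a log2 difference of 10.54 ± 0.48 (SE; limma adjusted p = 1.92e-09). HannXRQ_Chr13g0419741 was at 1463 ± 874 FPKM (SD, n = 3) in axil and at 0.0417 ± 0.0722 (SD, n = 3) in root. Each of these root levels rests on 1 read over the 3 libraries. Outside the axil, these 2 genes reached 907 and 323 FPKM. In the other direction, HannXRQ_Chr13g0424661 was at 0.613 ± 0.956 FPKM (SD, n = 3) in axil and 1808 ± 1250 (SD, n = 3) in root, a log2 difference of -10.06 ± 0.48 (SE; limma adjusted p = 3e-09). Its root mean was 1104 without Root 2, and its axil mean was 0.0610 without Axil 1. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes.

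Against stem, 3286 genes were higher in axil and 3702 lower. Which direction held the majority depended on the settings: more genes were higher with libraries scaled to the same sum (4426 against 3651), a pseudocount of 0.1 (4634 against 4498), adjusted p alone (7651 against 6290) and voom on recovered reads (4511 against 4463). HannXRQ_Chr12g0377421, already named for its axil level, was at 3.26 ± 5.12 FPKM (SD, n = 3) in stem, a log2 difference of 8.02 ± 0.79 (SE; limma adjusted p = 1.17e-05), and at 0.313 FPKM in stem without Stem 1. HannXRQ_Chr05g0161361 was at 823 ± 967 FPKM (SD, n = 3) in axil and 1.02 ± 0.961 (SD, n = 3) in stem, with means of 264 in axil without Axil 3 and 0.473 in stem without Stem 3. It also reached 2418 FPKM in Root 2. HannXRQ_Chr05g0143811 was lower, at 0.0441 ± 0.0433 FPKM (SD, n = 3) in axil and 438 ± 222 (SD, n = 3) in stem, with a log2 difference of -8.56 ± 0.99 (SE; limma adjusted p = 3.73e-05) and an axil mean of 0.0230 without Axil 1. The axil libraries differed in their distance to stem: the mean correlation with the stem libraries, across genes, was 0.851 for Axil 1, 0.803 for Axil 2 and 0.754 for Axil 3.

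Against leaf, 3600 genes were higher in axil and 2725 lower. HannXRQ_Chr01g0000161 was at 729 ± 591 FPKM (SD, n = 3) in axil and 2.52 ± 1.89 (SD, n = 3) in leaf, a log2 difference of 7.34 ± 0.71 (SE; limma adjusted p = 5.9e-06), and its axil mean was 443 without Axil 2. A pair of genes on chromosome 11 was far lower in axil. HannXRQ_Chr11g0325011 was at 2.97 ± 1.92 FPKM (SD, n = 3) in axil and 2098 ± 904 (SD, n = 3) in leaf, and HannXRQ_Chr11g0325331 was at 2.17 ± 0.488 (SD, n = 3) and 1715 ± 984 (SD, n = 3). Which direction held the majority depended on scaling: 56.9% of the called genes were higher in axil with FPKM as deposited, 65.5% with libraries scaled to the same sum, 45.8% after quantile normalization and 40.6% after median-of-ratios scaling. The median log2 difference of leaf minus axil over all genes was -0.202 as deposited and -0.329, -0.0476 and 0 under these scalings, in that order.

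Against flower, 4586 genes were higher in axil and 4719 lower. Neither direction held a stable majority: more genes were higher with libraries scaled to the same sum (5611 against 4830), a pseudocount of 0.1 (6164 against 5659), a filter at 5 FPKM (3650 against 3645), adjusted p alone (9113 against 7743) and voom on recovered reads (6004 against 5693). With the filter recomputed, the same held without Flower 2 (4535 against 4050), Flower 3 (4296 against 4139) or Axil 3 (4356 against 4323), and without both Flower 1 and Leaf 2 (4256 against 4251). With the filter kept from all 15 libraries it held without Flower 2 (4529 against 4455) and Axil 3 (4493 against 4323) and not without Flower 3 (4297 against 4563). HannXRQ_Chr03g0084471 was at 828 ± 749 FPKM (SD, n = 3) in axil and 0.655 ± 0.420 (SD, n = 3) in flower, a log2 difference of 8.59 ± 0.78 (SE; limma adjusted p = 2.13e-06), and its axil mean was 402 without Axil 3. It also reached 1419 FPKM in Leaf 3. The abundant flower gene HannXRQ_Chr17g0559971 was at 0.269 ± 0.123 FPKM (SD, n = 3) in axil, a log2 difference of -12.55 ± 0.18 (SE; limma adjusted p = 5.22e-14).

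The single gene that the table names is NAC83 (HannXRQ_Chr17g0568801, chromosome 17), a member of the NAC family of plant transcription factors. It was high in axil and root, intermediate in flower and low in stem and leaf. Its level was 44.2 ± 21.8 FPKM (SD, n = 3) in axil, 40.9 ± 19.1 in root, 10.8 ± 2.57 in flower, 2.36 ± 1.58 in stem (1.48 without Stem 2) and 0.963 ± 0.247 in leaf. Axil exceeded leaf by a log2 difference of 4.42 ± 0.43 (SE; limma adjusted p = 5.96e-06), stem by 3.74 (limma adjusted p = 3.52e-05) and flower by 1.84 (limma adjusted p = 0.00331). Root exceeded stem by 3.61 (limma adjusted p = 1.14e-05) and leaf by 4.29 (limma adjusted p = 2.15e-06). Axil and root differed by 0.13 ± 0.43 (SE; limma adjusted p = 0.852), less than the spread between replicates, and the sign turned without Root 1 (-0.34) or without Axil 3 (-0.23).

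**Figure D3:**
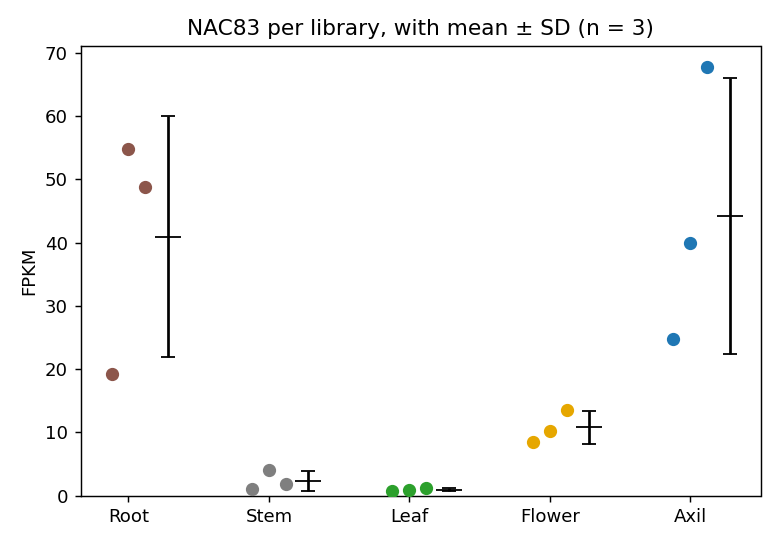
NAC83 expression in FPKM (vertical axis, from 0) in each library of the 5 tissues, with points for libraries and bars for the mean ± SD of 3 libraries. Axil libraries range from 24.8 to 67.7 FPKM and leaf libraries from 0.770 to 1.24.

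Identifier classes other than chromosomal genes were also compared between tissues. ENSRNA identifiers are the noncoding RNA class of the table. At the preset correlation they stood higher in leaf than in the mean of the other 4 tissues (camera adjusted p = 0.00277 over 30 tests), but not with an estimated correlation (camera adjusted p = 0.987). Of them, 30 were called higher (12.8%, against 8.99% of other genes), 7 lower and 197 not called. Identifiers not placed on a chromosome did likewise, with 18 of 72 higher and 3 lower (camera adjusted p = 0.029; adjusted p = 0.987 with an estimated correlation). Both calls were also lost under median-of-ratios scaling (adjusted p = 0.226). One leaf library, Leaf 2, and one flower library, Flower 1, held more reads of these classes than the rest: unplaced identifiers took 0.285% and 0.277% of their reads and at most 0.0670% in the other 13.

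**Figure D4:**
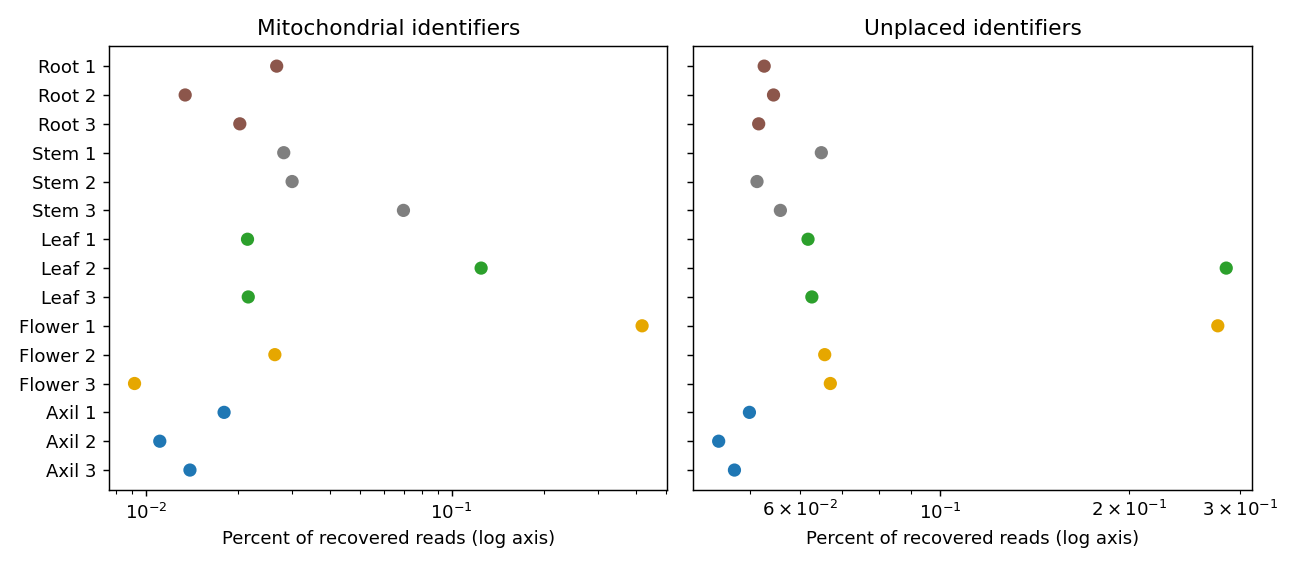
Percent of recovered reads (horizontal log axis) on mitochondrial (left) and unplaced (right) identifiers, with 1 point per library. Flower 1 and Leaf 2 lie at 0.419% and 0.125% on the left, above the highest of the other 13 libraries, 0.0695%.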

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

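The tests with limma's voom on recovered reads, without Flower 1 and Leaf 2, with an estimated correlation, and with the filter kept when a library is left out were chosen after the data were seen, as were the means of named genes without single libraries. Over 30 settings, 353 of 398 recomputed counts stayed within 1.5 times their reported value. The 865 recomputations of the 33 differences of NAC83 and of the genes taken by the rule kept their side of the threshold. Runs where the filter removed such a gene are not among them. Direction held too, except for NAC83 between axil and root, uncalled at 0.13 (-0.34 without Root 1, -0.23 without Axil 3). Apart from NAC83, these genes were taken for large differences in the same data, so kept calls say little about ordinary ones. The fixed gene lists and the TCP genes matched no identifiers, so their alternatives were not run. Genes close to the detection floor limit the counts: the pseudocount and the filter act on them.

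With a pseudocount of 5, the genes higher and lower in axil were 2300 and 2102 against root, 1453 and 1878 against stem, 1517 and 1502 against leaf, and 2186 and 2578 against flower. Genes higher than in each other tissue were then 1464 in root, 491 in stem, 705 in leaf, 950 in flower and 306 in axil. With adjusted p alone, the axil comparisons gave 8338 and 6246, 7651 and 6290, 8997 and 4301, and 9113 and 7743 in the same order. The genes of each tissue were 3930, 1459, 1830, 2434 and 1298. With a log2 difference of at least 2, the comparisons gave 1869 and 1778, 966 and 1237, 1038 and 1037, and 1533 and 1820. The genes of each tissue were 1210, 250, 412, 625 and 178. These thresholds move the counts by construction. With a filter at 5 FPKM, fewer genes were tested, and 2569 were lower in axil than root, 1591 were highest in root and 377 in axil.

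Leaving out 1 library, with the filter recomputed on the other 14, moved the root count from 2509 to between 1585 and 2562. It fell by over 1.5 times without any of the 3 root libraries (1596, 1585 and 1639), and no other count moved so far. A gene confined to root then has only 2 libraries and cannot pass a filter that asks for 3. The second run, made because of that fall and with the filter kept, left all 210 counts within 1.5 times, and the root count between 2445 and 2567. It shows that the filter accounts for the fall, and it does not replace the planned values.

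With voom, 6186 genes were higher in axil than root and 589 axil genes became 678. Without Flower 1 and Leaf 2, the camera tests in leaf gave adjusted p = 0.00497 for ENSRNA and 0.0257 for unplaced identifiers. Besides the main setting and that one, camera was run with an estimated correlation, median-of-ratios scaling and a replicate block, and not under the other settings. Over these runs the camera adjusted p ranged from 0.00252 to 0.987 for ENSRNA and from 0.0236 to 0.987 for unplaced. Replicate numbers are shared between tissues only as numbers. Deviations of same-numbered libraries correlated at a median of -0.0334 over 30 pairs, and 1 of 15 libraries correlated best with its own number. A replicate block gave 4705 genes higher in axil than root and 584 higher in axil than in each other tissue, and it moved no count by over 1.5 times and changed no call of a named gene. Scaling libraries to the same sum moved the median of leaf minus axil over all genes from -0.202 to -0.329, and that of root minus leaf from 0.145 to 0.345.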

Other observations

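The tests of the ENSRNA share, of Leaf 2 alone, of read-through in root and in the other tissues, of the axil libraries, of axil positions, of pairs of tissues and of shares of reads per identifier class were chosen after the result was seen. Among the 10 pairs of tissues, stem and flower shared the most genes higher in both than in each of the other 3, 899. Root and axil came next with 386, ahead of leaf and flower with 274 and leaf and axil with 201. Stem and axil shared 170 such genes. NAC83 met this criterion for root and axil, with flower the closest of the other tissues. The count for root and axil depended on the settings, with 168 at a pseudocount of 5, 605 at a pseudocount of 0.1 and 638 with libraries scaled to the same sum. Leaving out 1 library gave 287 to 518.

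Genes that mark the other 4 tissues were mostly low in axil. On a scale where 0 is the mean of the other 3 tissues and 1 the marked tissue, the median axil position was 0.239 for 1501 leaf genes, 0.150 for 3281 root genes, 0.133 for 1197 stem genes and 0.0196 for 1758 flower genes. These sets were defined without the axil libraries. The stem position rested on Axil 1: it was 0.314 in Axil 1, 0.0947 in Axil 2 and -0.00837 in Axil 3, and 0.0369 without Axil 1 and 0.218 without Axil 3. The flower position, near 0, was 0.00934 without Axil 1, 0.0114 without Axil 2 and 0.0383 without Axil 3. The leaf and root positions moved by less than 1.5 times without any axil library. Identifiers outside the chromosome, unplaced, organelle and ENSRNA classes formed a further class, of which 1383 were tested. They took 1.03% ± 0.157 of reads in root (SD, n = 3) and 0.677% ± 0.0471 in the other 12 libraries. Each root library (at least 0.887%) lay above each of the other 12 (at most 0.762%). The exact permutation p was 0.0022, the smallest the splits of 3 against 12 libraries can give, and 0.0549 after adjustment over 25 tests. That smallest p cannot pass the threshold alone over 25 tests, so the adjusted value decides nothing. Gene by gene, however, neither the share called higher nor camera showed this class raised in root. Among its 1383 tested identifiers, 13.3% were called higher in root than in the mean of the other 4 tissues, against 13.4% of other genes (camera adjusted p = 0.983). Fewer were called lower, 8.89% against 15.7% of other genes, and the median log2 differences were -0.0514 and -0.0538. Of 85 tests of tissue-preferential genes on single chromosomes, 0 passed the adjustment.

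Neighbouring identifiers on a chromosome shared tissue preference. Among adjacent pairs of tested genes, 782 had the same preference, against a mean of 310 in 1000 shuffles within chromosomes, and the number lay above all shuffles in 5 of 5 tissues, which argues against chance placement. Read-through from 1 gene into the next should stop at direct neighbours, but pairs 3 places apart were still 1.33 times the shuffled mean (415 against a highest shuffle of 367). Root carried most of this, at 1.37 times (239 against 213), whereas the other 4 tissues together, at 1.29 times, passed their highest shuffle by a single pair (176 against 175) and none of them passed it alone. The pairs at 3 places cannot exclude read-through for the larger excess at direct neighbours, 2.5 times the shuffled mean, so read-through stays open there. Reads shared between copies of a duplicated gene were not tested and stay open, so shared regulation of neighbours or local gene duplication may account for the pattern only as hypotheses.

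Axil 1 lay nearer to stem than the other axil libraries did. Over genes of stem, its median log2 ratio to Axil 2 and 3 exceeded the highest of the medians over genes of root, leaf and flower by 0.454. Of the stem genes, 77.8% were higher in Axil 1. That test restates the correlation with stem that was seen first, so whether the Axil 1 sample held more stem tissue stays open. Its depth of 12928827 reads (12.9 in units of 1e+06) lay within the range of the other libraries. It was above the 12094260 reads of Axil 2 and the 12162270 of Axil 3. A range over all tissues cannot tell whether depth mattered among the axil libraries, so depth stays open. A difference in the stage of the axil was not tested and stays open.

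Flower 1 and Leaf 2 held more organelle reads than the other 13 libraries. Their mitochondrial shares were 19.5 and 5.80 times the median of the others. Their ENSRNA shares, the lower of which was 0.0683%, both exceeded the highest of the others, 0.0594%, which is consistent with weaker selection of polyadenylated RNA. They still did without the 20 most abundant ENSRNA identifiers (0.0273% and 0.0254% against 0.0192%), but the median ENSRNA identifier was hardly raised over the other libraries of its tissue, by a log2 ratio of 0.05 in Flower 1 and 0 in Leaf 2, against 3.78 and 2.01 for mitochondrial identifiers. Genomic DNA could contribute and stays open: chromosome genes with reads in only that library of its tissue numbered 2158 in Leaf 2, above the 898 to 1471 of the others, and 1373 in Flower 1, within that range, while genes with reads in only that library of all 15 numbered 352 and 223, above the 98 to 209 of the others.

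Other groupings of the same libraries gave fewer genes with 1 exception. For genes that differ among tissues, 1 of 100 groupings, the real one, reached 28667, and the highest of the others gave 2108. The real grouping also gave the most genes higher than in each other tissue in root (2509, highest other 1), stem (903, highest other 218), leaf (1155, highest other 240) and flower (1565, highest other 0). The same held for the 386 genes of root and axil (highest other 0). The highest others for stem and leaf had the 3 axil libraries together in that place. For axil, 2 of 100 groupings reached 589, the real one and 1 other. The other one gave 1139, with the 3 flower libraries together in the place of axil, and so follows the structure of the samples. Groupings that mix tissues widen the spread within groups, which alone keeps their counts low. The 100 groupings thus show that libraries of a tissue belong together, and they cannot exclude chance for any single count. For axil against a single tissue the 10 splits are too few for a share under 0.05. The real values and highest others were 8616 and 21 for root, 6988 and 3 for stem, 6325 and 8 for leaf, and 9305 and 1 for flower.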
